A study of Mus musculus with 14 samples.

How the data were processed

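Gene expression was measured by RNA sequencing in 14 single cells from the bones of adult Prrx1-CreERT;Tomato mice on the C57BL/6 background. In this line a tamoxifen-dependent Cre recombinase is made where the Prrx1 promoter is active, and recombination switches on the red fluorescent reporter Tomato, so that a red cell is one that used this promoter at the time of tamoxifen or descends from such a cell. Per the labels' protocols, tamoxifen was injected once a day for 3 days at 2 mg per 30 g of body weight. Marrow was flushed out of the tibia, radius and ulna, the bones were washed, minced and digested with collagenase, and red cells were sorted and then picked singly under a fluorescence microscope. The libraries were made with a SMART-Seq v4 3' kit, which captures the 3' end of polyadenylated transcripts, and a Nextera XT kit, per the labels' protocols.

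TopHat2, Cufflinks and the genome build GRCm38 are named in the submitters' processing notes, with no version. The deposited table is named for FPKM (fragments per kilobase of transcript per 1000000 mapped), but its values are on a log2 scale, read here as log2(FPKM + 1), and hold the same distribution in every cell, as after quantile normalization. Neither step is recorded in the labels or the file header, so both readings rest on the values. The largest value was 14.58 in each of the 14 columns. Over the 7304 ranks that were above 0 in every cell, the 14 values at a rank differed by at most 0.0246. Back-transformed as powers of 2, the values summed to between 646250 and 646278 per cell, whereas natural logarithms would have given sums of at least 17114801, far above what FPKM values can reach for transcripts of usual length. Values at 0 stayed at 0, and their number differed between cells.

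The processing limits what the values can show. Quantile normalization gives each cell the same total and the same number of genes above a given level, apart from the lowest values, so a difference in RNA content or depth between cells cannot be seen, and a value ranks a gene within its cell. The depth of the libraries is unknown, since the table holds no counts, and no interval or detection limit that needs the depth is given. FPKM divides by transcript length although reads from a 3' kit do not grow with length, so long genes are understated against short ones. The table holds 9558 rows for 9549 gene IDs. Each row reached at least 1.61 in some cell, and how the rows were chosen is not given in the sources used here. Of these rows, 9544 matched GENCODE M21 (GRCm38) by Ensembl ID and 98.0% were protein-coding. No row had a symbol beginning with mt-, and mitochondrial transcripts were not analysed here. For a repeated symbol the first row was used. All 14 value columns were matched to a sample by title, and 0 columns were left over.

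The labels put all 14 cells into 1 group and name no animal. Cells are not replicates of an animal, so the cells count as 1 sample, no test between samples was possible, and no p-value or standard error is given. Values are reported per cell, or as the median, range and SD over the 14 cells, which describe these cells only. Exact Clopper-Pearson 95% intervals of a share of cells cover counting error only. Before the data were examined, 30 gene lists, the comparisons and the rule for named genes were fixed. The plan assumed linear FPKM values, so its thresholds were carried to the log2 scale: a gene was counted as detected at a value of 1 or more, which corresponds to an FPKM of 1. The gene lists were Prrx1 alone, skeletal stem and progenitor, osteoblast, osteocyte, chondrocyte, adipocyte, tendon, fibroblast matrix, smooth muscle and pericyte, endothelial, pan-haematopoietic, erythroid, neutrophil, macrophage and monocyte, osteoclast, B cell, T and NK cell, mast cell, basophil and megakaryocyte, skeletal muscle, Schwann and neural, cell cycle, immediate early and stress, housekeeping, BMP and TGF-beta, Wnt, Hedgehog, growth factor receptors, Notch, limb patterning and haematopoietic niche factors. They hold 225 distinct genes with a row. List members without a row are left out of every count and percentile, which so rest on the members that passed the unknown choice of rows. Named genes are list members, the 15 genes with the highest mean over the cells and the 15 with the largest SD among genes detected in 5 to 9 cells, leaving out ribosomal protein, mitochondrial, predicted and small nucleolar RNA or microRNA symbols.

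Computed from the table were, per cell, the number of detected genes and the mean of each list. Each list's mean detection and mean level over the cells were placed among 10000 random lists of the same size drawn from the rows, as a description of these libraries. The mean over the stem, osteoblast and fibroblast matrix lists together (56 genes) minus the mean over the pan-haematopoietic, neutrophil, macrophage and B cell lists together (29 genes) was taken within each cell. The erythroid list belonged to the second sum but had no analysed member. Spearman correlations between cells used the 9101 rows with a mean back-transformed value of 1 or more. No doublet caller was run, since 14 picked cells are too few, and no cell was given a type. Average-linkage clustering of which genes were above 0, chosen after the data had been seen, split the cells into the 2 sets described with the correlations; genes at 7 or more in 1 cell and 4 or less in the rest were left out of it. Alternatives chosen beforehand were other detection thresholds, rescaling to 1000000 per cell, other pseudocounts, a filter on low genes, protein-coding rows only, undoing the length division with exon lengths, another correlation, and leaving out each cell in turn. Setting cells 11 and 14 aside, setting cells 6, 8, 11 and 14 aside, and a threshold of 5 on the log2 scale were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Tested on simulated data over 9558 genes, the random-list step placed 19 of 20 lists with raised detection above the 95th percentile, and 3 of 100 unchanged lists. Over 4000 simulated genes in 2 pools, the clustering put 14 of 14 cells into their pool when reads crossed within pools and 7 of 14 when none did; a split with another cause was not simulated.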

Results

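The data comprised the transcript levels of 14 Tomato-positive cells picked from digested adult mouse bone, numbered 1 to 14 as in the labels. All cells carried the same genotype and treatment, so the design held 1 group and asked what the cells marked through the Prrx1 promoter express. No comparison between conditions could be made, and the comparisons below are between genes and gene lists within these cells. Between 7304 and 8027 of the 9558 gene rows were above 0 per cell. The number of rows at 1 or more was 5066 in every cell, which the quantile normalization sets. In total 1506 rows were detected in all 14 cells and 4939 in at least 7. Levels are given as log2 quantile-normalized FPKM.

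Prrx1, the homeobox transcription factor of limb mesenchyme whose promoter drives the Cre recombinase, was detected in 11 of 14 cells (78.6%, exact 95% interval 49.2% to 95.3%). The gene (ENSMUSG00000026586) lies on the minus strand of chromosome 1 from 163245119 to 163313710 in GRCm38. Its level was 3.24 ± 2.15 (SD, 14 cells), with a median of 3.53. Cell 1 had the highest level at 7.31, followed by cell 3 at 5.98 and cell 9 at 5.06. Cells 2, 12 and 14 held 0.61, 0.52 and 0.59, below the detection level. At an FPKM of 10 or more, 7 cells had Prrx1, and at a log2 value of 5 or more, 3 cells did. Its paralogue Prrx2 was detected in 9 cells, with 9.68 in cell 1 and 6.30 in cell 13.

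Genes of the skeletal stem and progenitor list were compared with Prrx1 in the same cells. Of the 21 measured members of the list, 13 were detected in at least 7 cells, 8 in fewer and 3 in all 14. Its mean detection, 58.8% against 53.0% over all rows, lay at the 79.7th percentile of the random lists and so was not set apart from them. Ly6a, which encodes the stem cell antigen Sca-1, had a median of 10.71 (range 4.94 to 13.22), Cd200 had 6.45 (3.59 to 12.56) and the hyaluronan receptor Cd44 had 6.04 (2.53 to 7.58), each in all 14 cells. Pdgfra, a receptor widely used to mark mesenchymal progenitors, was detected in 11 cells with a median of 3.84, whereas Pdgfrb was detected in 4 cells. The integrin subunit Itgav was detected in 13 cells, with a median of 4.13.

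The stromal genes of the haematopoietic niche were unevenly spread over the cells. Cxcl12, the chemokine of reticular stromal cells, was detected in 13 cells and reached 11.38 in cell 9 against a median of 3.92. The leptin receptor gene Lepr was detected in 12 cells and reached 10.56 in cell 2 and 9.97 in cell 7, with a median of 3.02. Cxcl12 was at 6.87 in cell 7 and 3.97 in cell 2, and cell 9 had Lepr at 6.12. Cells 6, 7 and 9 held both genes at 5 or more, cell 2 only Lepr and cell 11 only Cxcl12. Grem1, a BMP antagonist gene, reached 8.25 in cell 12 and was detected in 6 cells. Gli1, a Hedgehog target, was detected in 3 cells and was highest in cell 7 at 4.13. Nes was detected in 1 cell, cell 13, at 3.72, and Mcam in 2 cells, with 5.33 in cell 12. Thy1 was detected in 7 cells and Vcam1 in 10.

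**Figure D1:**
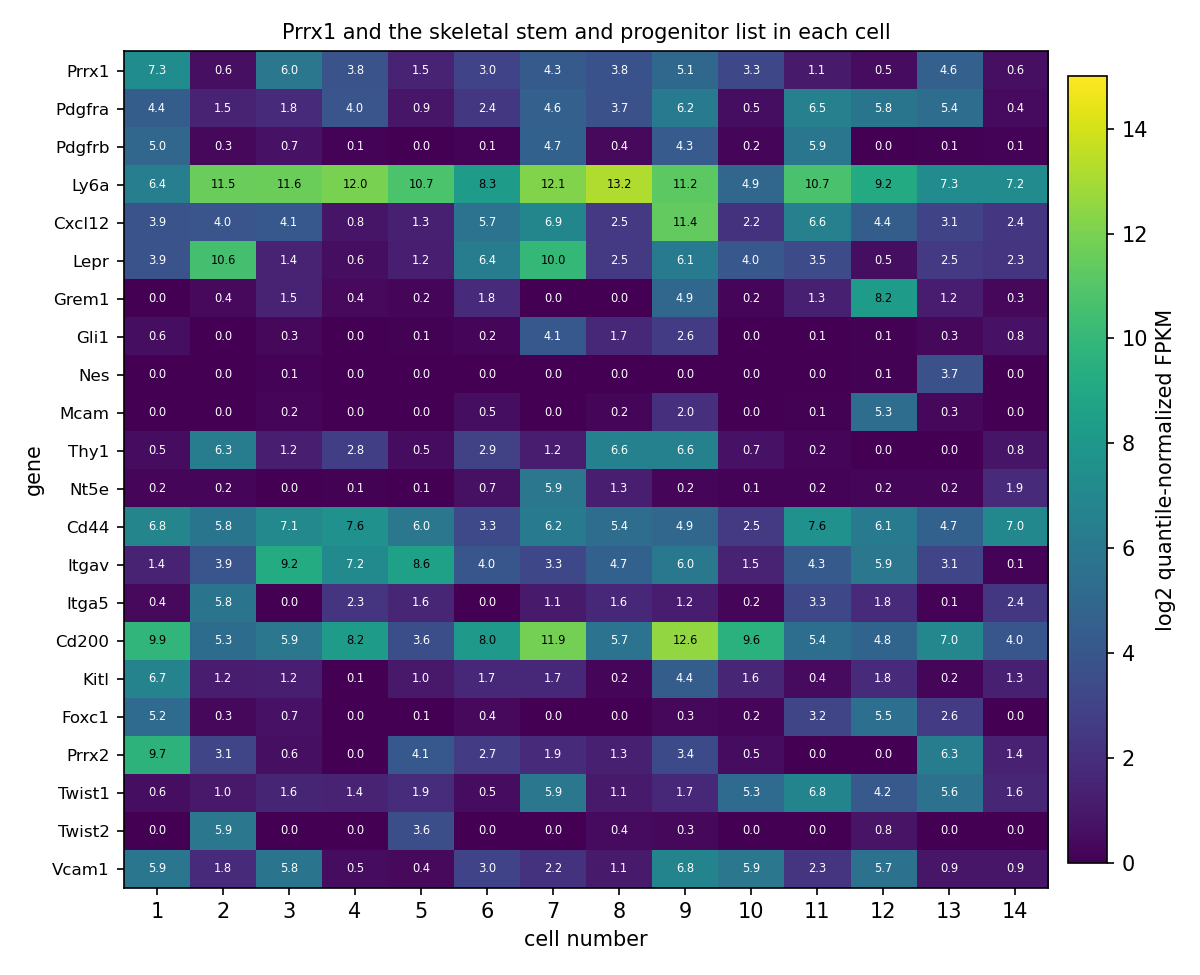
Level of Prrx1 and of the 21 measured skeletal stem and progenitor genes (vertical axis) in each of the 14 cells (horizontal axis), as log2 quantile-normalized FPKM given by colour and number. Ly6a, Cd44 and Cd200 were at 1 or more in all 14 cells, while Nes was at 1 or more only in cell 13.

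Detection of these markers together with Prrx1 was counted over the cells. Ly6a, Cd44, Cd200 and Itgav were each detected in all 11 cells with Prrx1, Cxcl12 and Lepr each in 10 of them, and Pdgfra and Twist1 each in 9. Outside them, the 3 cells without detected Prrx1 all had Ly6a, Cd44, Cd200, Cxcl12 and Twist1, 2 of the 3 had Pdgfra, and 2 had Lepr. In total 11 of the 21 markers were found with Prrx1 in at least 7 cells, a count that was 4 at an FPKM of 5 or more and 3 at an FPKM of 10 or more, where Prrx1 itself was left in 9 and 7 cells. With 3 cells lacking Prrx1, a dependence between Prrx1 and any marker was not tested.

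Genes of the fibroblast extracellular matrix were the most widely detected of the tissue lists. All 22 members had a row and were detected in at least 7 cells, 17 of them in all 14. The small proteoglycan gene Dcn (decorin) had the highest mean of the named genes, with a median of 12.62 (range 7.04 to 14.58) and an SD of 2.23. It was the highest value of the whole table in cells 2, 7 and 8. Pcolce, an enhancer of procollagen processing, had a median of 10.06, Serpinf1 of 9.79, Lum of 9.0, the calcification inhibitor Mgp of 8.77 and the collagen gene Col3a1 of 7.07. The list mean ranged from 3.36 in cell 14 to 8.68 in cell 1. Its mean detection, 96.1% of cell and gene pairs, lay at the 100th percentile of the random lists.

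Osteoblast genes divided into widely detected matrix genes and genes high in few cells. Of 13 measured members, 8 were detected in at least 7 cells and 6 in all 14. The type I collagen genes Col1a1 and Col1a2 had medians of 7.45 and 8.78, and Sparc (osteonectin) of 11.50. Ibsp, which encodes the bone sialoprotein of mineralized matrix, was at 12.48 in cell 10 and 11.17 in cell 13 against a median of 3.87. Ifitm5, an osteoblast membrane protein gene, was at 11.72 in cell 6, 10.60 in cell 13 and 9.0 in cell 10, with a median of 2.33. The osteopontin gene Spp1 reached 13.82 in cell 10. The transcription factor genes Runx2 and Sp7 were detected in 4 and 3 cells. Cells 10, 13 and 6 had the highest list means, at 8.44, 8.26 and 6.92, and the lowest was cell 14 at 2.52. Prrx1 in these 3 cells was at 3.28, 4.62 and 3.04. Of the osteocyte list, 3 members were measured and 1, Pdpn, was detected in at least 7 cells, while Dmp1 was detected in 2, at 6.42 in cell 11 and 5.25 in cell 13.

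Chondrocyte and adipocyte genes were at lower levels. Of 14 chondrocyte genes fixed, 7 were measured, and 4 of these were detected in at least 7 cells. Sox9, the chondrogenic transcription factor, was detected in 7 cells with 5.66 in cell 1, and the cartilage collagen gene Col2a1 in 7 cells with 9.53 in cell 13. Col11a2 reached 9.96 in cell 6 and Comp 8.13 in cell 7. Of 12 adipocyte genes fixed, 7 were measured. Among them 3 were detected in at least 7 cells, namely Fabp4 in 14 cells with a median of 6.66, Cebpb in 12 and Lpl in 12. The adipogenic factor Cebpa was detected in cell 7 alone, at 4.32, and the lipid droplet gene Plin1 in 5 cells. Mean detection lay at the 28.0th percentile of random lists for chondrocyte genes and at the 46.5th for adipocyte genes, against the 96.15th for osteoblast genes. At least 2 detected members of each of the osteoblast, chondrocyte and adipocyte lists were found together in 11 of 14 cells. Random lists were not set against this count. Mean detection over all rows was 53.0%, a rate at which other lists of this size would often reach 2 members in a cell. The joint count therefore does not set these lists apart. Taken alone, the osteoblast list had at least 2 detected members in all 14 cells at every threshold tried. The number of such cells was 7 at an FPKM of 5, 5 at an FPKM of 10 and 3 at a log2 value of 5, the last being cells 1, 6 and 13.

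Tendon, smooth muscle and endothelial lists had mean detection of 60%, 33.9% and 58.6%. Of 5 measured tendon genes, 3 were detected in at least 7 cells, with Fmod at 9.02 in cell 1 and 7.14 in cell 5, Thbs4 at 10.45 in cell 11, and Scx, the tendon transcription factor, at 5.74 in cell 5. Of 4 measured smooth muscle and pericyte genes, 1 was detected in at least 7 cells, and Acta2 reached 6.13 in cell 14 and 5.80 in cell 4. With cells 11 and 14 set aside, 0 of these 4 genes were detected in at least 6 of 12 cells. Of 5 measured endothelial genes, 3 were detected in at least 7 cells, Pecam1 in 13 with a median of 2.99 and a maximum of 7.07 in cell 6.

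**Figure D2:**
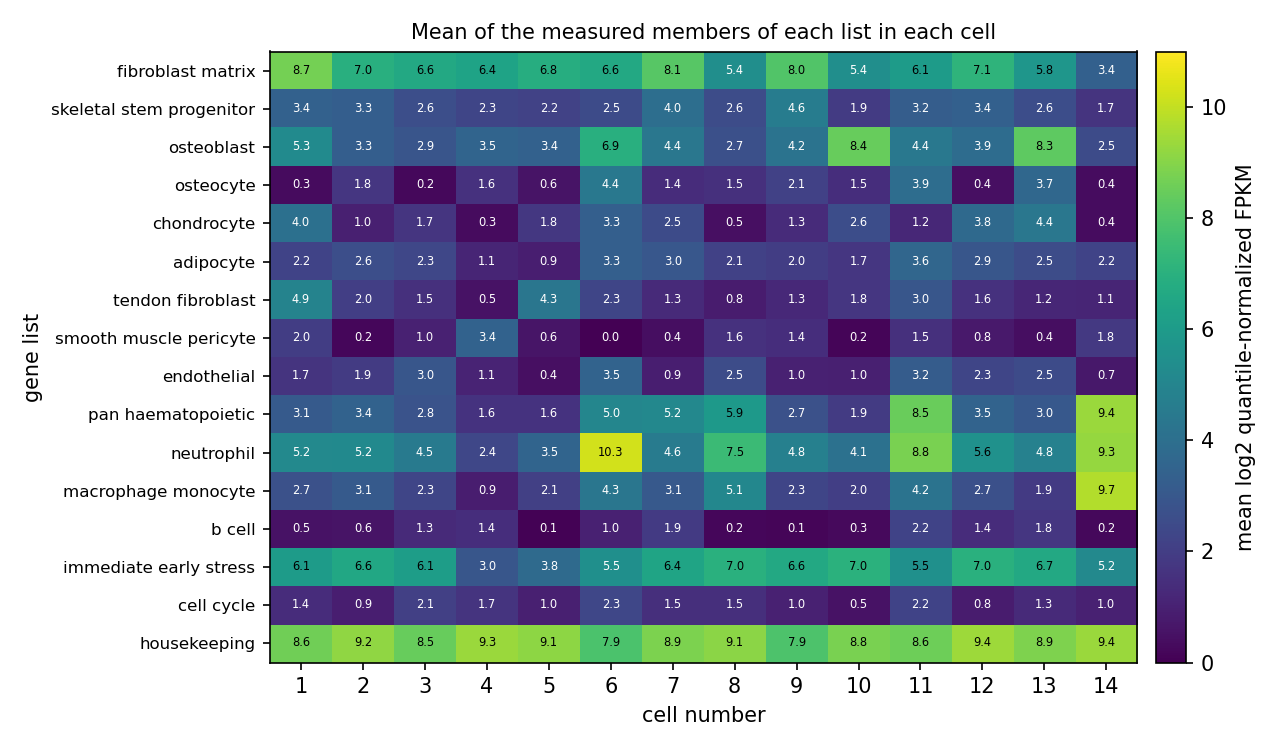
Mean log2 quantile-normalized FPKM over the measured members of 16 gene lists (vertical axis) in each of the 14 cells (horizontal axis), given by colour and number. The osteoblast list was highest in cells 10 and 13, at 8.44 and 8.26, and the pan-haematopoietic list in cells 14 and 11, at 9.36 and 8.48.

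Blood cell genes were examined because the flushed bones had held marrow. Of 10 pan-haematopoietic genes, 7 were detected in at least 7 cells and 4 in all 14. Ptprc, which encodes the leukocyte antigen CD45, was detected in 5 cells, at 8.31 in cell 11 and 6.51 in cell 14, with a median of 0.46. The list mean was 9.36 in cell 14 and 8.48 in cell 11, and between 1.63 and 5.95 in the other cells. Of 10 measured neutrophil genes, 8 were detected in at least 7 cells. The granule protein gene Camp had a median of 9.64 (range 6.44 to 12.96), Retnlg of 9.92 (5.47 to 14.58) and Ngp of 8.70 (4.19 to 12.77), each in all 14 cells. The early granule genes Mpo and Elane were at 11.25 and 8.13 in cell 6 and were detected in 5 and 3 cells. Mean detection of the neutrophil list lay at the 99.4th percentile of random lists and that of the pan-haematopoietic list at the 97.0th. The neutrophil list mean was highest in cell 6, at 10.26, followed by cell 14 at 9.26, cell 11 at 8.81 and cell 8 at 7.52. Setting cells 11 and 14 aside left 8 neutrophil genes, 6 pan-haematopoietic genes and all 22 fibroblast matrix genes detected in at least 6 of the 12 other cells, and setting cells 6 and 8 aside as well left the same 3 counts in at least 5 of 10 cells.

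Of 5 measured macrophage genes, 3 were detected in at least 7 cells. They had their highest list mean in cell 14, at 9.74, where Lyz2 was at 13.56, Cd14 at 11.58, Ctss at 9.06 and Cd68 at 8.65. Cd68 was detected in 4 cells. Of 3 measured osteoclast genes, 2 were detected in at least 7 cells. Of these Ctsk was detected in all 14 cells with a median of 6.48, and Mmp9 in 11, with 9.29 in cell 14. The 2 genes were not high in the same cells: Ctsk was highest in cell 12, at 9.32, where Mmp9 was at 0, and lowest in cell 14, at 1.97. Acp5, the osteoclast acid phosphatase gene, was detected in 4. It was above 0 only in cells 3, 4, 11, 12 and 13, the smaller of the 2 sets described with the correlations. Of 4 measured B cell genes, 1, Ms4a1, was detected in at least 7 cells, with a median of 1.07. The erythroid and T cell lists were not analysed here.

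The stem, osteoblast and fibroblast matrix genes together were set against the blood cell genes within each cell. The first mean exceeded the second in 10 of 14 cells, by a median over all cells of 1.38 log2 units (SD 2.43, range -5.60 to 2.87). Cells 6, 8, 11 and 14 had the reverse order, with differences of -1.0, -1.84, -2.37 and -5.60. Cell 14 had a mean of 2.53 over the first set and 8.13 over the second, while cell 11 had 4.62 and 6.99. Dcn was at 7.04 in cell 14, the lowest of all cells, and at 12.28 in cell 11. Without the neutrophil list the median difference was 2.05, positive in 11 cells. Undoing the division by transcript length gave 2.38, with 10 cells positive.

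Immediate early and stress genes were at high levels in most cells. All 16 were detected in at least 7 cells and 11 in all 14, with a median of 9.70 for Fos and 7.50 for both Junb and Zfp36. The list mean was lowest in cells 4 and 5, at 2.96 and 3.78, and ranged from 5.16 to 7.03 in the others. In contrast, of 16 cell cycle genes fixed, 9 were measured and 3 were detected in at least 7 cells. Of these Pcna was detected in 14 cells, Birc5 in 9 and Tyms in 7, while Top2a and Cdk1 were detected in 4 and 1. The 11 measured housekeeping genes were each detected in at least 7 cells and 9 in all 14, with an SD over the cells of 0.57 for Eef1a1, the lowest of the list, and 2.55 for Pgk1, the highest.

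The 15 genes with the highest means included, after Dcn, the ferritin gene Ftl1 (mean 11.98), Eif1 (11.85), the calcium-binding protein gene S100a11 (11.84), B2m (11.61), Sparc (11.52) and the protease inhibitor gene Cst3 (11.36). The genes with the largest SD among those detected in 5 to 9 cells began with the small non-coding RNA genes Rny1 (SD 4.84) and Rnu11 (4.22), short genes that the division by length overstates. Other genes were also among the 15 with the largest SD. They included Fap, the fibroblast activation protein gene, with an SD of 3.92 and levels of 10.34 in cell 12, 9.35 in cell 10, 9.04 in cell 13 and 8.23 in cell 6 against a median of 1.56.

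The cells were compared with one another across genes, which are not independent replicates. The median Spearman correlation over the 91 pairs was 0.469, with a lowest value of 0.372 for cells 4 and 6 and a highest of 0.610 for cells 4 and 5. Cell 14 had the lowest median correlation with the others, 0.431, and cell 2 the highest, 0.510. The cells were also clustered by which genes were at 0. Without the genes high in 1 cell only, cells 1, 2, 5, 6, 7, 8, 9, 10 and 14 formed one set and cells 3, 4, 11, 12 and 13 the other. Correlations of levels followed these sets in part. They were 0.511 to 0.590 among cells 3, 11, 12 and 13, and 0.439 to 0.516 between these cells and cell 4. For pairs of cells from different sets they were 0.372 to 0.610. Over all 5165 rows not above 0 in every cell, the correlation of presence was 0.273 in the median within sets and 0.105 between them. The sets were defined from the values and are not groups of the labels. Prrx1 was detected in 7 of 9 cells of the larger set and in 4 of 5 of the smaller. The median difference between the mesenchymal and blood cell means was 1.57 in the larger set and 1.18 in the smaller.

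**Figure D3:**
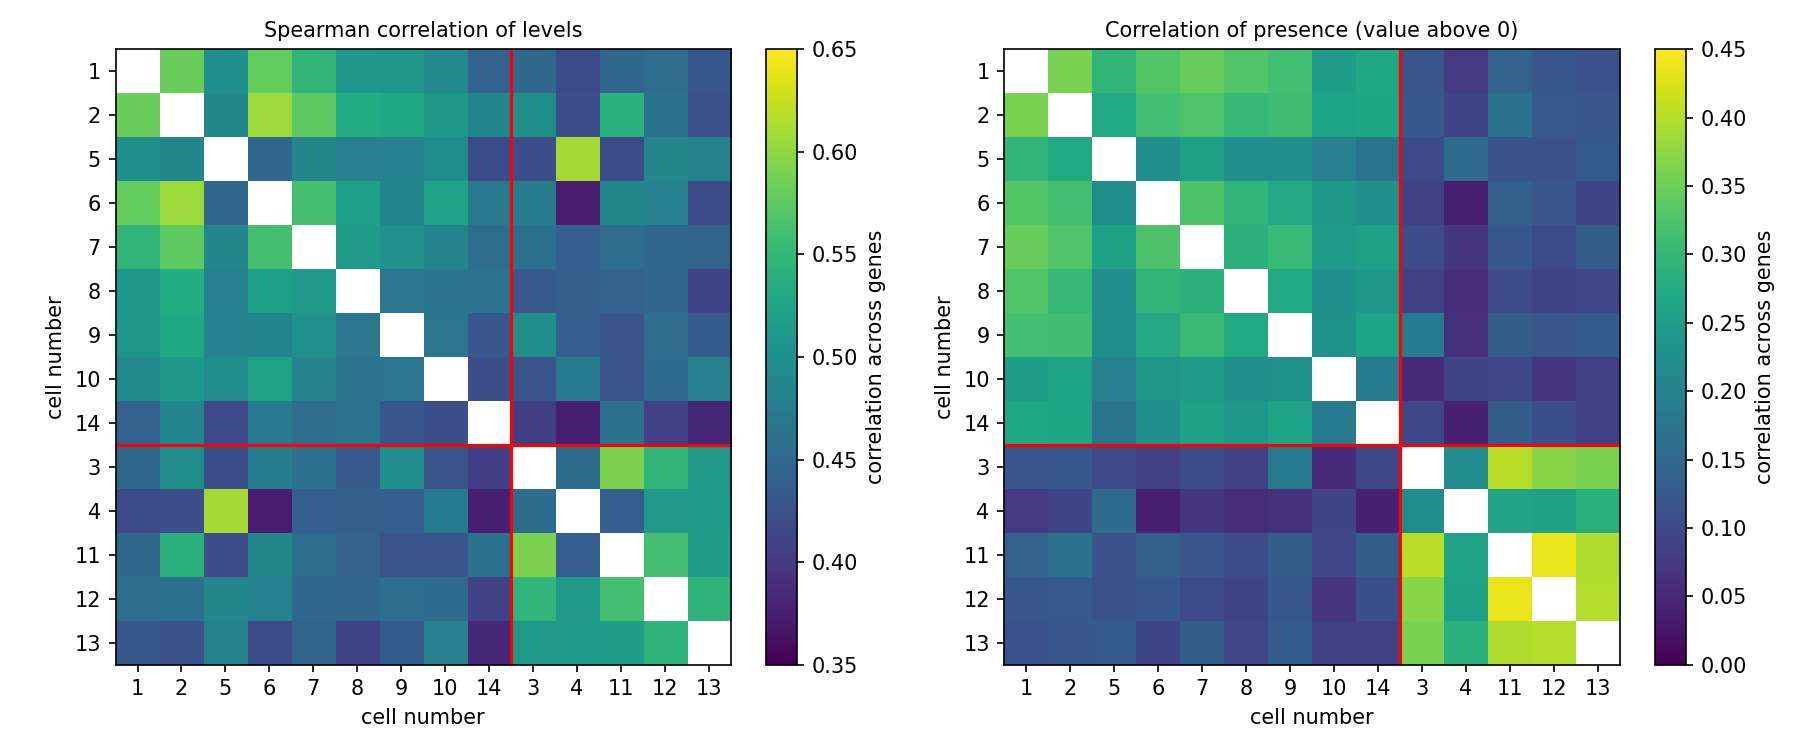
Spearman correlation of levels across 9101 genes (left) and correlation of presence, a value above 0, across 5165 genes (right) between each pair of the 14 cells, with cell numbers on both axes and the red lines parting the 9 cells and 5 cells of the presence split. Presence correlations were 0.174 to 0.437 within the sets and 0.0373 to 0.185 between them. Level correlations were 0.511 to 0.590 among cells 3, 11, 12 and 13. Cells 4 and 5, on either side of the split, had the highest level correlation, 0.610.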

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

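No test was run between samples, so the alternatives show how far each value moves, and the added settings (a log2 value of 5, 12 cells without cells 11 and 14, and 10 cells without cells 6, 8, 11 and 14) were chosen after the data had been seen. The number of genes per cell followed the threshold: 7771 above 0, 3372 at an FPKM of 5, 2726 at an FPKM of 10, 5537 after rescaling to 1000000 and 4971.5 for protein-coding rows only, against 5066. Genes in every cell numbered 4393 above 0, 594 at an FPKM of 5, 405 at an FPKM of 10 and 235 at a log2 value of 5, against 1506. Cells with Prrx1 numbered 7 at an FPKM of 10 and 3 at a log2 value of 5, against 11. Cells with at least 2 detected members of each of the 3 lineage lists numbered 11. At an FPKM of 5, an FPKM of 10 and a log2 value of 5 they numbered 7, 5 and 3. Stem markers found with Prrx1 in at least 7 cells numbered 19 above 0, then 4, 3 and 0 at the same 3 thresholds, against 11, and the 0 is forced, since Prrx1 itself is then left in 3 cells. List genes detected in at least 7 cells numbered 86 at an FPKM of 10 and 64 at a log2 value of 5, against 133. The stem list went from 13 to 7 at an FPKM of 5 and of 10 and to 3 at a log2 value of 5. The osteoblast list went from 8 to 13 above 0 and to 5 at a log2 value of 5, the pan-haematopoietic list from 7 to 4 at an FPKM of 10 and at a log2 value of 5, and the neutrophil list from 8 to 5 at a log2 value of 5. The fibroblast matrix and immediate early lists stayed within 1.5 times their counts at every threshold tried. The median mesenchymal minus blood cell difference stayed positive in all its alternatives, from 1.08 (pseudocount 10) to 2.38 (length division undone). With each cell left out it was either 1.18 or 1.57, the 2 middle values of the 14 cells. That range follows from taking a median and does not measure the spread, as single cells ranged from -5.60 to 2.87. Leaving out the erythroid list moved nothing, as it has no analysed member. The median correlation between cells was 0.419 to 0.507 over the other filters and measures, and 0.464 to 0.482 with each cell left out. The 12-cell and 10-cell settings moved none of the counts above by over 1.5 times. Of the 20 other lists they moved 3 and 1: smooth muscle to 0 and Schwann to 2 in 12 cells, and limb patterning to 2 in both. These settings also lower the number of cells asked for, from 7 to 6 and 5, and the Schwann and limb patterning rises in 12 cells come from that alone. The library depth is unknown, so what it limits was not measured.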

Other observations

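The gene lists in this part were fixed before the data were examined, and the tests of explanations were all chosen after the values had been seen. Signalling lists differed in how widely they were detected. Of 20 measured BMP and TGF-beta genes, 11 were detected in at least 7 cells, and the inhibitor of differentiation genes Id2 and Id3 were in all 14 with medians of 8.24 and 10.36, while Id3 was at 2.56 to 3.55 in cells 4, 5 and 14. The receptor genes Bmpr2 and Tgfbr1 were detected in 13 and 11 cells, and Bmpr1a in 3. Of 12 Wnt genes, 4 were detected in at least 7 cells, with Lrp6 in 13 and Ctnnb1 in 11. None of 4 measured Hedgehog genes was detected in at least 7 cells, and cell 9 was the only cell with all 4. Of 14 growth factor and receptor genes, 5 were detected in at least 7 cells, with Fgfr1 in all 14 and Igf1 at 10.28 in cell 7 and 9.74 in cell 1. Of 5 Notch pathway genes, Hes1 and Rbpj were in all 14 cells, and the other 3 in fewer than 7.

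Limb patterning genes were sparse: none of 8 measured members was detected in at least 7 cells, and the list lay at the 0.295th percentile of random lists for mean detection. Hoxa9 was at 6.24 in cell 1, Shox2 at 5.77 in cell 10, Msx1 at 6.92 in cell 3 and Tbx15 at 6.17 in cell 2. Of 8 measured niche factor genes, 5 were detected in at least 7 cells, and their mean was highest in cell 9, at 5.18, where Cxcl12, Vcam1 and Il7 were at 11.38, 6.78 and 5.5. Of 4 Schwann and neural genes 1, Mbp, was detected in at least 7 cells. Of the mast cell, basophil and megakaryocyte list 2 genes were measured and 0 were detected in at least 7 cells, and of the skeletal muscle list 1 was measured, Tnnt3, detected in 6 cells and at 7.01 in cell 1. Tnnt3 was above 0 only in cells 1, 2, 5, 6, 7, 9 and 10, which all belong to the larger presence set. Cells 4 and 5, the pair with the highest correlation of levels, had the highest Timp1, at 12.01 and 12.39, and the highest S100a10 levels, at 13.56 and 12.96. S100a4, named after its values were seen, was at 13.82 and 14.58 in them, and their immediate early list means were the lowest.

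The first pattern is the split of the cells into sets of 9 and 5 by which genes are at 0. Genes at 7 or more in 1 cell and at 4 or less in the rest, 277 in all and left out when the sets were made, were above 0 in 73.8% of the other cells of the same set and in 50.0% of the cells of the other set, a difference of 23.8 percentage points that held in direction for 12 of the 14 cells and not for cells 9 and 10. Any cause of the split gives some such difference, so the 224 of these genes not above 0 in every cell were set against 4941 other genes matched on the number of cells above 0: the differences were 28.2 and 11.8 points, an excess of 16.4, which is consistent with reads or molecules crossing between libraries handled together, as a hypothesis under which low values in a cell may not be its own RNA. The matched genes differ in level as well and the labels give no batch, so other causes of the split stay open. For a difference in cell type, the within-set minus between-set correlation of presence was compared between thresholds. It was 0.168 above 0, 0.0335 at 1 or more and -0.0193 at 5 or more. The sets were made from presence above 0, so a fall at higher thresholds can come with any cause and cannot decide on cell type. A difference in the number of genes above 0 as the whole cause is argued against by the range of the larger set. Of the smaller set, 4 of 5 cells lay inside it.

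The second pattern is neutrophil RNA in every cell, in a preparation that was flushed of marrow, washed, sorted for Tomato and picked singly. Reads crossing from the libraries of neutrophil-rich cells were considered as a hypothesis. Over the 10 neutrophil genes, which are not independent replicates, the levels in cells 11 and 14 and the medians of the other 12 cells had a Spearman correlation of 0.976. Those in cells 6, 8, 11 and 14 and the other 10 cells had one of 0.939. Any source of neutrophil RNA could give such an order within neutrophil genes, so these correlations do not decide on crossing. Other blood genes were not part of the comparison. Tyrobp was at 12.14 and 12.65 in cells 11 and 14 with a median of 5.86 over all 14 cells, against 12.39, 11.52 and 7.63 for Lcn2. Srgn, at 11.85 and 12.39, had a median of 8.05. Quantile normalization keeps order and not ratios of levels, so a single rate of crossing could not be tested, and a common outside source, such as free neutrophil RNA in the digest, predicts the same order. For such a source, the 10 cells other than 6, 8, 11 and 14 had a median pairwise Pearson correlation of 0.890 over these genes, above the 0.621 of the immediate early list, the only list first compared, but close to the 0.855 of the osteoblast list, added after the value was seen along with the matrix list (0.567). Crossing and an outside source cannot be told apart by these values and both stay open, and expression by the cells themselves, an attached blood cell and any biological explanation were not tested.

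Several cells hold markers of more than 1 cell type, given here as values. Cell 6 had 85 of the 277 genes that were high in 1 cell only, the most of any cell, and combined Ifitm5 at 11.72 and Col1a2 at 11.97 with Mpo at 11.25 and Ly6g at 10.67, and its highest genes were the small RNAs Rn7sk and Rnu11 at 14.58 and 13.82. Rn7sk was named after its values were seen. Small RNAs are short, so the division by length overstates them. Cell 6 also had the lowest housekeeping list mean, 7.87, and the quality of its library was not measured. Cell 11 combined Dcn at 12.28 and Pdgfra at 6.55 with Ptprc at 8.31 and Retnlg at 14.58. Cell 14 had Prrx1 at 0.59, Lyz2 at 13.56 and the lowest fibroblast matrix mean, 3.36. The platelet factor gene Pf4 was at 8.47 in cell 13, at 1.69 to 2.22 in cells 3, 11 and 12, and listed at 0 in the other 10 cells.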
